A study of Mus musculus with 6 samples.

How the data were processed

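RNA was measured in 6 mouse cochlear organoid cultures grown from epithelial cells of wild-type mice at postnatal day 5. Per the labels' protocols, cells received a control lentivirus (mCherry and an HA tag) or a lentivirus with human TRIM71 and mCherry before plating, and RNA was taken after 10 days in an expansion medium that held EGF, FGF2, CHIR99021 (an inhibitor of GSK3), an inhibitor of the TGF-beta receptor TGFBR1 and VPA (valproic acid, an inhibitor of histone deacetylases). Libraries were made with a stranded total RNA kit and sequenced from both ends with reads of 50 bases, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, which gave 3 control and 3 TRIM71 libraries. The design text speaks of independent samples from different animals without saying that a number marks an animal.

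The authors deposited a table per library with the length, the effective length and the estimated count of each of 118489 transcripts. The submitters' processing notes name kallisto, which assigns reads to transcripts, and sleuth, which tests transcripts, both without a version. The transcript index and genome build were not given in the sources used here. Estimated counts can be fractional, because a read that matches several transcripts is shared between them. Genes with near-identical copies, such as the replication-dependent histones and the ribosomal protein genes with their pseudogenes, therefore have less certain values than single-copy genes. Whether reads of the human TRIM71 transgene were assigned to the mouse Trim71 transcript cannot be read from these tables.

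Of the transcripts, 116728 (98.5%) had the same versioned identifier as a transcript of GENCODE mouse release 21 (assembly GRCm 38), each with an identical length. The other 1761 transcripts, which held between 0.567% and 0.656% of the estimated counts of a library, were left out. Estimated counts were summed over the transcripts of each of 35968 genes and rounded to whole numbers before testing. Coordinates are 1-based positions of that release. Totals ran from 21495644 to 33675806 estimated counts per library, and 18226 to 19126 genes had at least 10 counts in a library. The most abundant gene, Igfbp5 (chosen after its values were seen), held between 0.516% and 1.81% of the counts. No pair of libraries of the same group differed only by sampling noise: the chi-square statistic per degree of freedom, over genes with at least 20 counts in the pair, lay between 22.5 and 70.9.

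The test for genes was the robust quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM factors and the filterByExpr filter, which kept 18790 genes, with group as the term and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Values after ± beside log2 fold changes are standard errors, taken as the fold change divided by the square root of the F statistic, and every comparison had n = 3 libraries per group. Beside mean fold changes of lists they are standard errors over the list members. Levels are given as CPM (counts scaled to a common library size with TMM factors), computed here. Transcripts were tested in the same way. Lists of genes were tested with camera of limma 3.58.1 on voom values, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 36 lists. Of these lists, 32 were fixed by name and 4 by a pattern of gene symbols, all before the data were examined. List members were also counted after adjustment over the list alone.

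The rule for named genes was likewise fixed before the data were examined. It took Trim71, 17 further genes chosen in advance, the 10 largest rises and the 10 largest falls among called genes with an average log2 CPM of at least 2, separate groups and a symbol that was not a predicted model or pseudogene, and up to 4 members of each list with the smallest p. It gave 164 genes, of which the text describes a part. Genes outside the rule are named with the remark that they were chosen after their values were seen. For genes with 1 to 3 counts summed over a group, the ratio of summed counts scaled by effective library size is given with an exact 95% interval, which covers counting error only.

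Replicate numbers were shared between the groups, so the correlation of each library's deviations from its group mean (log2 CPM, prior count 2) was checked. It was 0.433, 0.228 and 0.374 for libraries of the same number, all over the bound of 0.1 set beforehand, and between -0.331 and -0.0482 for different numbers. Deviations within a group cancel out, so positive values for the same number in part force negative values for different numbers. The values therefore leave pairing by number possible without settling it, and the labels do not state it. The main fit was kept without the number. The fit with the number as a replicate block is given where it changed a call or moved the number of called members of a list by more than 1.5 times.

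The alternatives planned before the data were examined were DESeq2 1.42.0, RLE and upper-quartile factors, library totals without factors, no filter beyond a total count of 1, at least 10 counts in all libraries, counts scaled from TPM and gene length, protein-coding genes only, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate block, a test against a 1.5-fold change (glmTreat), and each library left out in turn. For lists they were an estimated correlation and fry. With an estimated correlation camera also takes its p from the few residual degrees of freedom of the libraries. A call lost in that setting therefore does not measure the correlation between genes alone. Counts from protein-coding transcripts only were added after seeing the data.

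The gene test was checked on simulated counts with the means, library sizes and dispersions of these data. Over 18300 simulated genes with 200 changed, it recovered 10.4% of the 1.5-fold changes, 68.7% of the 2-fold changes and 97.0% of the 4-fold changes. The changed genes were drawn only from those above a minimum mean count in controls, so these shares do not cover genes with few counts. It made 7 false calls, 5.65% of all its calls, and 0 calls had the wrong direction. With no gene changed it made 4 calls. On such counts camera called a list of raised genes (adjusted p = 3.51e-40) and 0 of 39 unchanged lists. The simulated genes varied independently, so this does not show how list tests behave with correlated genes. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.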

Results

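RNA was sequenced from cochlear organoids, cultures that grow from single epithelial cells of the mouse inner ear, after infection with a control lentivirus or with a lentivirus that expressed human TRIM71. TRIM71 (LIN-41) is an RNA-binding protein of early embryos whose mRNA is a classical target of the microRNA let-7. The comparison asks which RNAs differed between organoids with and without the transgene after 10 days of expansion, in a study on the reprogramming of supporting cells, the non-sensory neighbours of hair cells. Each group had 3 libraries. The control libraries held 24973671, 24545943 and 21495644 estimated counts and the TRIM71 libraries 29386847, 33675806 and 21536217, so depth did not separate the groups.

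Mouse Trim71 (chromosome 9, 114507133 to 114564369) stood at 14.8, 39.6 and 19.9 CPM in control 1, 2 and 3 and at 90.8, 123 and 113 CPM in TRIM71 1, 2 and 3. It rose by 2.14 ± 0.37 on the log2 scale, a 4.41-fold difference (edgeR adjusted p = 0.00909), in the direction the labels give. The call was narrowly lost without control 3 (adjusted p = 0.0502). The deposited tables do not separate reads of the human transgene from those of the mouse gene.

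**Figure D1:**
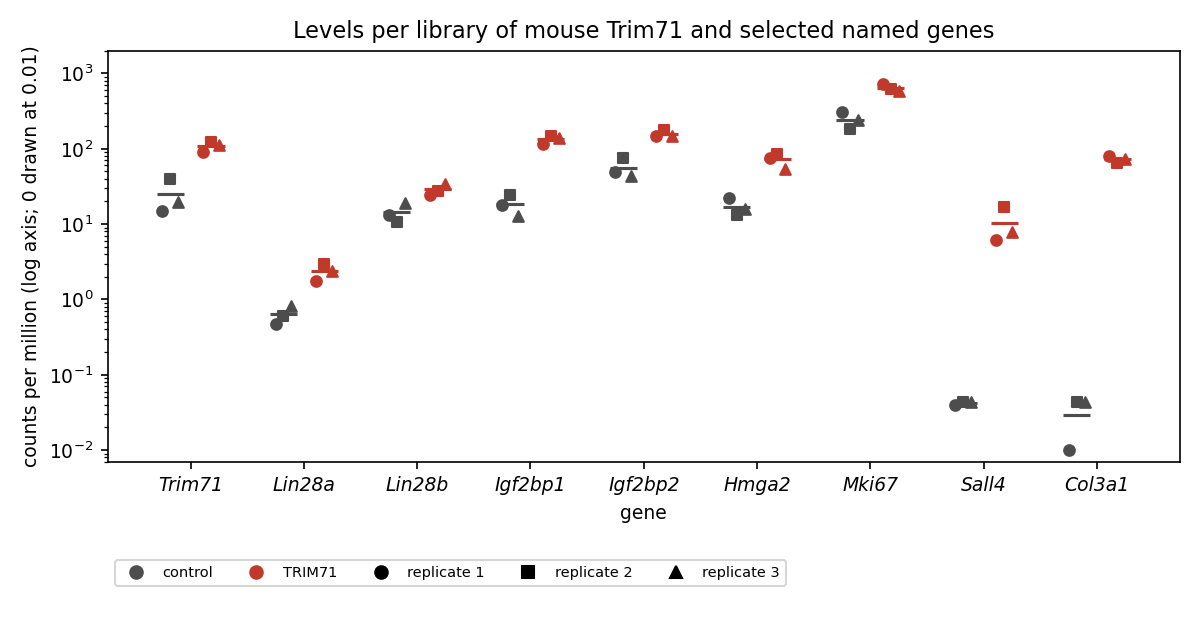
CPM (vertical axis, log scale) of 9 genes (horizontal axis) in each library; grey symbols are controls and red symbols TRIM71 libraries, the symbol shape gives the replicate number and the bars are group means. Every TRIM71 library lies above every control library for these genes, with Trim71 between 14.8 and 39.6 CPM in controls and between 90.8 and 123 CPM in TRIM71 libraries.

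Organoids with TRIM71 had higher levels of Igf2bp1, Hmga2 and Mki67 and lower levels of Otoa. Camera called the lists of G2 and M phase, of let-7 and LIN28, of prosensory and progenitor, and of mesenchymal genes as higher, calls that were all lost with an estimated correlation (adjusted p = 0.247, 0.247, 0.297 and 0.249 with an estimated correlation). Igf2bp1, an oncofetal RNA-binding protein (chromosome 11, 95957163 to 96005940), rose from 18.5 ± 5.97 to 134 ± 15.6 CPM (mean ± SD, n = 3 each), and Hmga2, a chromatin protein of proliferating progenitors (chromosome 10, 120361275 to 120476469), rose from 17.0 ± 4.47 to 72.1 ± 16.6 CPM. The proliferation marker Mki67 (chromosome 7, 135689784 to 135716361) rose 2.65-fold, from 243 ± 61.3 to 644 ± 65.4 CPM. Otoa, which encodes otoancorin of the tectorial membrane attachment (chromosome 7, 121081650 to 121163097), fell by 3.84 ± 0.51 on the log2 scale, from a control mean of 1132 ± 332 CPM to 78.8 ± 40.3 CPM. The adjusted p of these 4 genes lay between 0.000234 and 0.00404.

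Across the transcriptome, 4626 of 18790 tested genes passed an adjusted p of 0.05: 2466 rose and 2160 fell. At least 2-fold changes were seen in 1795 called genes (1026 rose, 769 fell), and 453 changed at least 4-fold (287 rose, 166 fell). All TRIM71 libraries lay on the same side of all control libraries for 43.3% of tested genes, where chance gives 10%. The number of called genes was 2293 without control 1, 6976 without control 2, 2208 without TRIM71 2 and 2669 without TRIM71 3. Genes called with all libraries and with each of the 6 left out numbered 1923, each in the same direction throughout. A test against a 1.5-fold change called 1110 genes and ended the calls of 47 of the 141 called genes that the naming rule gave. The first principal component of log2 CPM held 58.4% of the variance and placed controls 1, 2 and 3 at -59.9, -27.0 and -65.9, and TRIM71 1, 2 and 3 at 41.4, 59.7 and 51.7.

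The largest rises included genes that were close to absent in controls. Col3a1, a fibrillar collagen (chromosome 1, 45311538 to 45349706), had 2 counts over the 3 controls and 5927 over the TRIM71 libraries, a scaled ratio of 2568 with a counting interval from 711 to 21208. Crabp1, a retinoic acid-binding protein, had 3 against 902 counts (ratio 261, interval 88.9 to 1266), and the embryonic transcription factor Sall4 had 3 against 889 counts (ratio 257, interval 87.6 to 1247). Slitrk6, a transmembrane protein of the developing inner ear, rose by 7.38 ± 0.32 on the log2 scale, and Cbln2 by 6.95 ± 0.90. The platelet-derived growth factor receptor gene Pdgfrb rose by 6.41 ± 0.60, Zpld1 by 5.54 ± 0.42, the autotaxin gene Enpp2 by 5.39 ± 0.35 and Cped1 by 4.76 ± 0.31. All counts of Cbln2 in controls came from control 2 (0, 0.479 and 0 CPM in controls 1, 2 and 3), so the size of its rise is uncertain. Without control 2 the controls held 0 counts, and the log2 fold change of 12.02 then depends on the small count that the fit adds. Without control 1 the log2 fold change was 6.34. That of Pdgfrb was 7.59 without control 2 and 5.79 without control 1. The limma test on log2 TPM, which adds a pseudocount of 1, gave 3.60 for Slitrk6, 3.72 for Cbln2, 2.74 for Pdgfrb and 2.59 for Zpld1. Postn, the matricellular protein periostin, rose by 7.41 ± 1.09, but its call was lost without control 1 (adjusted p = 0.0646), and its log2 fold change was 9.18 without control 2.

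The largest falls were those of Agr3, which fell by 4.82 ± 0.34 on the log2 scale, and Mgll, monoacylglycerol lipase (chromosome 6, 88724412 to 88828360), which fell by 4.49 ± 0.15 from 68.4 ± 7.49 to 3.01 ± 0.37 CPM. The metalloreductase gene Steap4 fell by 4.27 ± 0.33, Ano5 by 3.75 ± 0.44, complement C3 by 3.67 ± 0.43, the prostaglandin D synthase gene Ptgds by 3.45 ± 0.24 and the matricellular gene Smoc2 by 3.45 ± 0.54. A2ml1 fell by 4.42 ± 0.90 and Shisa9 by 3.45 ± 0.74. The call of A2ml1 was lost without control 1, control 3 or TRIM71 2 (adjusted p = 0.1002, 0.0887 and 0.0708), and that of Shisa9 without control 1, control 3, TRIM71 1 or TRIM71 3 (adjusted p = 0.0794, 0.0700, 0.0534 and 0.0588). Without a filter on counts both calls were lost (adjusted p = 0.0560 and 0.0642), and that of A2ml1 also with counts scaled from TPM (adjusted p = 0.0572). Without TRIM71 1 the log2 fold change was -5.79 for A2ml1, -4.39 for Ano5 and -4.10 for Smoc2, and counts scaled from TPM gave -2.79 for C3.

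Genes of cell division rose together. Of 54 tested G2 and M phase genes 52 rose (52 adjusted over the list alone), and 0 fell. Cdca8, of the chromosomal passenger complex, rose by 1.57 ± 0.11 on the log2 scale, the anaphase activator Cdc20 by 1.45 ± 0.11, the mitotic kinase Aurka by 1.47 ± 0.11 and the kinetochore motor Cenpe by 1.87 ± 0.16. The 2 members that did not pass, Ctcf and Jpt1, had log2 fold changes of -0.20 and 0.20 (chosen after their values were seen). The list stood above the other genes by camera (adjusted p = 6.60e-30; adjusted p = 0.247 with an estimated correlation). Of 67 replication-dependent histone genes 59 rose (61 adjusted over the list alone), and 0 fell, among them Hist1h1d by 1.74 ± 0.11 and Hist1h3g by 2.08 ± 0.15 (camera adjusted p = 4.55e-28; adjusted p = 0.247 with an estimated correlation). These genes are near-identical in part, so the split between single members is uncertain.

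Of 43 S phase genes 21 rose (24 adjusted over the list alone), and 0 fell. The uracil glycosylase gene Ung rose by 0.98 ± 0.12, the DNA methylation partner Uhrf1 by 1.31 ± 0.16 and Cdca7 by 1.12 ± 0.16 (camera adjusted p = 4.84e-08; adjusted p = 0.470 with an estimated correlation). The number of called S phase genes was 7, 8 and 10 without TRIM71 1, 2 and 3, and 11 with library totals in place of TMM factors. Among 16 cell cycle inhibitors, Cdkn2c and Cdkn2d rose by 0.91 ± 0.17 and 1.35 ± 0.26, and Cdkn1c fell by 1.68 ± 0.30 (6 rose and 1 fell adjusted over the list alone). The list was not called (camera adjusted p = 0.0555), but passed with the replicate block (adjusted p = 0.0203), without control 2 (0.0128), without TRIM71 1 (0.0314) and with library totals (0.0473). It had an adjusted p = 0.472 with an estimated correlation, and 0.516 with the block as well. With the block 8 members rose and 1 fell, without control 2, 6 and 1, and with protein-coding transcripts only 4 and 1. Library totals called 6. Cdkn1a had a log2 fold change of 0.91 ± 0.46 (adjusted p = 0.198) and Cdkn1b of 0.45 ± 0.15 (adjusted p = 0.0627), and both passed with the block (adjusted p = 0.00517 and 0.0193) and without control 2 (1.53 with adjusted p = 0.00961, and 0.62 with adjusted p = 0.00666). Cdkn1b also passed with DESeq2 (0.0458) and library totals (0.0406).

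Of 36 targets of let-7 and genes of the LIN28 axis 17 rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 2.90e-06; adjusted p = 0.247 with an estimated correlation). Igf2bp1 rose by 2.86 ± 0.23 on the log2 scale, Hmga2 by 2.09 ± 0.23, the imprinted retrotransposon-derived gene Peg10 by 2.78 ± 0.19 and the phosphatase gene Cdc25a by 0.93 ± 0.10. Igf2bp2 rose by 1.49 ± 0.21, while Igf2bp3 had a log2 fold change of 0.24 ± 0.09 (adjusted p = 0.0897, and 0.0399 with protein-coding transcripts only). With counts scaled from TPM the rise was 2.02 for Igf2bp1 and 0.83 for Igf2bp2, and with protein-coding transcripts only it was 2.68 for Hmga2. Lin28a, an inhibitor of let-7 maturation (chromosome 4, 134003330 to 134018841), rose by 1.89 ± 0.35 from 0.633 ± 0.172 to 2.36 ± 0.594 CPM. Its call was lost with counts scaled from TPM (adjusted p = 0.121) and with limma on log2 TPM with a pseudocount of 1 (0.0848) or 0.1 (0.0969). Its paralog Lin28b (chromosome 10, 45376620 to 45486395) rose by 1.01 ± 0.22 from 14.3 ± 4.27 to 28.9 ± 4.84 CPM. It lost its call without control 1 (adjusted p = 0.0511), with counts scaled from TPM (0.0734), with limma on log2 TPM with a pseudocount of 1 (0.155) or 0.1 (0.150) and against a 1.5-fold change (0.137). The member that fell was Tet3, by 0.40 ± 0.11 (chosen after its values were seen; adjusted p = 0.105, 0.0710, 0.122 and 0.0771 without control 1, TRIM71 1, TRIM71 2 and TRIM71 3).

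Of 11 mRNAs that earlier work had named as TRIM71 targets, Ago2 and Inhba rose, by 0.47 ± 0.12 and 0.89 ± 0.26, and 0 fell (1 rose adjusted over the list alone). Both calls were lost without any 1 library other than control 2: for Inhba the adjusted p was 0.130, 0.128, 0.0834, 0.117 and 0.123 without control 1, control 3, TRIM71 1, TRIM71 2 and TRIM71 3, and for Ago2 0.0906, 0.0560, 0.0538, 0.0929 and 0.0589. The call of Inhba was also lost without a filter on counts (adjusted p = 0.0887) and with counts scaled from TPM (0.0697). Without control 2, 4 members rose and 1 fell, and with the block 4 rose and 0 fell. The list had a camera adjusted p = 0.0934, which was 0.0498 with the block, and fry called it as higher (adjusted p = 0.0396). It had an adjusted p = 0.337 with an estimated correlation (0.492 with the block as well). Egr1 had a log2 fold change of -0.43 ± 0.23 (adjusted p = 0.215). It was called as lower without control 2 (-0.61, adjusted p = 0.0391) and stood at -0.16 without control 1. Tgfbr1 had a log2 fold change of -0.10 ± 0.11 (adjusted p = 0.559). Without 1 library at a time it lay between -0.18 (without control 2) and -0.04 (without TRIM71 2), and Tgfbr1 was not called in any of these fits. Of 10 tested pluripotency genes, Sall4, Lin28a and Klf4 rose, and Tfcp2l1 and L1td1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.559). The median log2 fold change of this list was -0.01 and its mean 0.88. Called members numbered 3 without control 1, 3 without control 3 and 2 without TRIM71 2, and L1td1 was chosen after its values were seen (adjusted p = 0.149, 0.0891, 0.131 and 0.158 without control 1, control 3, TRIM71 1 and TRIM71 2). The call of Klf4 was lost without control 1, TRIM71 2 or TRIM71 3 (adjusted p = 0.0640, 0.0717 and 0.0554) and that of Tfcp2l1 without control 3, TRIM71 1 or TRIM71 2 (adjusted p = 0.0508, 0.0551 and 0.0820).

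**Figure D2:**
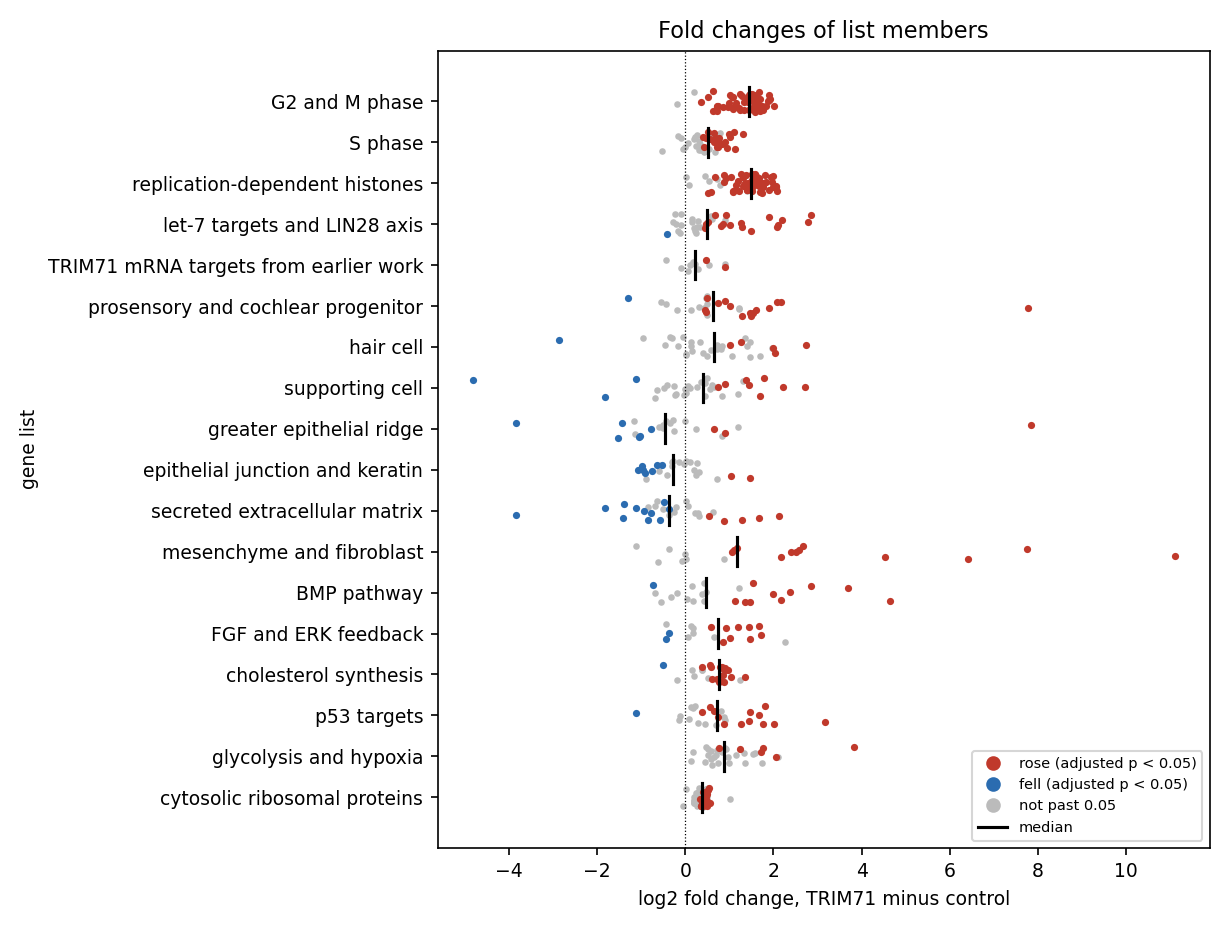
Log2 fold change, TRIM71 minus control (horizontal axis), of each tested member of 18 gene lists (vertical axis); red points rose and blue points fell at an adjusted p under 0.05, grey points did not pass, and the black bar is the list's median. The G2 and M phase list lies to the right of 0 with 52 of 54 members risen, whereas the secreted extracellular matrix list spreads to both sides, with 5 risen and 11 fallen.

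Of 28 prosensory and cochlear progenitor genes 15 rose and 1 fell (19 and 1 adjusted over the list alone; camera adjusted p = 8.83e-06; adjusted p = 0.297 with an estimated correlation). Besides Hmga2 and Sall4, Bmp4, which marks the outer edge of the prosensory domain, rose by 2.18 ± 0.29 on the log2 scale (2.78 with limma on log2 TPM with a pseudocount of 0.1), and the homeobox gene Hmx3 fell by 1.29 ± 0.18. Called progenitor genes numbered 9 without control 1 and 10 without TRIM71 2 or TRIM71 3. Lgr5, a Wnt-responsive marker of supporting cell progenitors (chromosome 10, 115450311 to 115587780), rose 1.68-fold from 263 ± 17.9 to 441 ± 30.4 CPM. Sox2, expressed in prosensory and supporting cells, stood at 7.53 ± 1.32 and 10.7 ± 4.80 CPM (adjusted p = 0.325). It was called as higher without TRIM71 1 (log2 fold change 0.84 in place of 0.50, adjusted p = 0.0369) and stood at 0.31 without TRIM71 2 (adjusted p = 0.640) and 0.29 without TRIM71 3 (adjusted p = 0.636).

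Of 32 hair cell genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0360; adjusted p = 0.656 with an estimated correlation). Atoh1, the transcription factor that starts hair cell fate (chromosome 6, 64729125 to 64731245), rose by 2.75 ± 0.62 from 0.501 ± 0.412 to 3.36 ± 1.63 CPM, and lost its call without control 3 (adjusted p = 0.0664) or TRIM71 2 (adjusted p = 0.0600). Without control 2 it stood at 3.63. Rbm24 rose by 1.99 ± 0.35, whereas Pcdh15, a component of the tip link of hair bundles, fell by 2.86 ± 0.27. The otoferlin gene Otof rose by 2.03 ± 0.48, and its call was lost without control 1, control 3, TRIM71 2 or TRIM71 3 (adjusted p = 0.0533, 0.0980, 0.0717 and 0.0685) and with counts scaled from TPM (0.0642). Without control 2 its log2 fold change was 2.64. Dll1 and Barhl1 completed the 5 and were chosen after their values were seen (Dll1 adjusted p = 0.124, 0.0744, 0.123 and 0.124 without control 1, control 3, TRIM71 2 and TRIM71 3; Barhl1 adjusted p = 0.145, 0.0604, 0.156 and 0.103 without control 1, control 2, TRIM71 2 and TRIM71 3). Pou4f3 had a log2 fold change of 1.47 ± 0.61 (adjusted p = 0.120), but passed with the block (adjusted p = 0.00434), with DESeq2 (0.0217) and without TRIM71 1 (0.0409), and stood at 2.07 without control 2. With the block 11 hair cell genes rose and 1 fell, and without control 2, 9 and 2. The number called was 3 without control 1, control 3, TRIM71 2 or TRIM71 3. The list's call was lost without control 1 (adjusted p = 0.115) and without TRIM71 3 (adjusted p = 0.0847), with fry (adjusted p = 0.278) and with protein-coding genes only (adjusted p = 0.0547).

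Of 34 supporting cell genes 8 rose and 3 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.0864). The Notch effector Hey2 rose by 2.73 ± 0.26 on the log2 scale and the neurotrophin receptor gene Ngfr by 1.78 ± 0.24, while Otogl, a tectorial membrane protein, fell by 1.81 ± 0.24 and the potassium channel gene Kcnj10 by 1.12 ± 0.20, beside Agr3. Without control 2 the list was called with 16 members risen and 4 fallen (adjusted p = 0.0142), and without TRIM71 1 it was also called (adjusted p = 0.0223). With all libraries it had an adjusted p = 0.508 with an estimated correlation. In the greater epithelial ridge, the transient epithelium next to the inner hair cells, 3 of 22 genes rose and 6 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.0934). Cpxm2 fell by 1.52 ± 0.14, Ccn2 by 1.43 ± 0.21, Ptn by 1.02 ± 0.17 and Otoa as above, while Crabp1, Crabp2 (chosen after its values were seen) and Gata2 rose. The greater epithelial ridge list was called as lower with the block (adjusted p = 0.0383), without control 3 (adjusted p = 0.0151) and without TRIM71 2 (adjusted p = 0.0284), but had an adjusted p = 0.567 with an estimated correlation (0.555 with the block as well). Of 11 genes of Reissner membrane, outer sulcus and roof, Meis2, Fgf9, Lgr5 and Gata2 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0213; adjusted p = 0.295 with an estimated correlation), and 7 rose without control 2. Gata2 lost its call without any 1 library other than control 2, with adjusted p = 0.141, 0.0761, 0.0981, 0.141 and 0.0654 without control 1, control 3, TRIM71 1, TRIM71 2 and TRIM71 3, and also with RLE factors (0.0514), without a filter (0.0951) and with counts scaled from TPM (0.0713).

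Of 19 mesenchyme and fibroblast genes 12 rose (13 rose and 1 fell adjusted over the list alone), and 0 fell (camera adjusted p = 2.90e-06; adjusted p = 0.249 with an estimated correlation). Col1a2 rose by 4.53 ± 0.29 on the log2 scale and the transcription factor Prrx1 by 2.66 ± 0.19, and Twist2 had 2 counts over the controls against 590 (ratio 256, interval 70.4 to 2116). The most abundant members, Lum and Dcn (chosen after their values were seen), stood at 1182 ± 445 and 654 ± 340 CPM in controls and at 1193 ± 142 and 651 ± 167 CPM in TRIM71 libraries. Of 22 genes of epithelial to mesenchymal transition 8 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.00123; adjusted p = 0.297 with an estimated correlation), and 5 were called without control 1. The integrin gene Itga5 rose by 3.30 ± 0.25, Lox by 1.91 ± 0.31 and Snai2 by 1.46 ± 0.25. With counts scaled from TPM the rise of Itga5 was 1.53, and with protein-coding transcripts only that of Col1a2 was 7.03. Mmp2 (chosen after its values were seen) fell by 1.01 ± 0.18.

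Of 24 epithelial junction and keratin genes 2 rose and 7 fell (3 and 11 adjusted over the list alone; 4 and 9 with the block; camera adjusted p = 0.0934). The E-cadherin gene Cdh1 (chromosome 8, 106603351 to 106670246) fell by 1.08 ± 0.20 on the log2 scale from 469 ± 73.8 to 221 ± 57.2 CPM. The transcription factor Grhl2 fell by 0.75 ± 0.10, the splicing regulator Esrp2 by 0.96 ± 0.16 and Krt7 by 0.99 ± 0.17. Ovol1 and Elf3 rose (both chosen after their values were seen; Elf3 adjusted p = 0.0743, 0.0898, 0.0517, 0.0829 and 0.0820 without control 1, control 3, TRIM71 1, TRIM71 2 and TRIM71 3). None of Cdh1, Grhl2, Esrp2 and Krt7 passed the test against a 1.5-fold change. Epcam stood at 561 ± 116 and 419 ± 5.95 CPM (adjusted p = 0.0732). It was called as lower with DESeq2 (adjusted p = 0.0428), upper-quartile factors (0.0296), library totals (0.0218), protein-coding transcripts only (0.0344) and without control 3 (0.0344), while without control 2 its log2 fold change was -0.24 in place of -0.42 (adjusted p = 0.0985). Without control 2, 7 junction genes rose and 9 fell, and without control 3 the list was called as lower (adjusted p = 0.00898), with an adjusted p = 0.663 with an estimated correlation over all libraries. Of 29 secreted matrix genes 5 rose and 11 fell (5 and 13 adjusted over the list alone; camera adjusted p = 0.0862). The collagen genes Col11a1 and Col11a2 fell by 1.11 ± 0.12 and 1.39 ± 0.15, while the basement membrane genes Lama1 and Nid2 rose by 1.28 ± 0.14 and 1.67 ± 0.19. Lama3, Col4a1 and Col4a2 rose as well (chosen after their values were seen; Col4a2 adjusted p = 0.0538, 0.0505, 0.0670 and 0.0718 without control 1, control 3, TRIM71 2 and TRIM71 3). Called matrix genes numbered 10 without control 1, 9 without TRIM71 2 and 10 without TRIM71 3. The matrix list was called as lower with the block (adjusted p = 0.0498), without control 3 (adjusted p = 0.0113) and without TRIM71 2 (adjusted p = 0.0445), but had an adjusted p = 0.601 with an estimated correlation (0.572 with the block as well).

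Markers of other cochlear cell types did not move in 1 direction. Of 14 genes of stria and melanocytes 1 rose and 5 fell (1 and 6 adjusted over the list alone; 3 and 6 with the block; camera adjusted p = 0.0353; adjusted p = 0.295 with an estimated correlation), a call that was lost without control 2 (adjusted p = 0.116). The potassium channel gene Kcnq1 fell by 2.40 ± 0.20 on the log2 scale, with Kcnj10 and Tfcp2l1 (adjusted p = 0.0508, 0.0551 and 0.0820 without control 3, TRIM71 1 and TRIM71 2) among the others that fell, and Kit rose by 1.14 ± 0.23. Of 20 neuronal genes Ina, Nefl, Scn9a, Snap25 and Nefm rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.0708), with 11 risen and 3 fallen under the block, and 2 called without control 1 and 3 without TRIM71 2. Nefm was chosen after its values were seen (adjusted p = 0.123, 0.105, 0.0814 and 0.0941 without control 1, control 2, TRIM71 2 and TRIM71 3). Without control 1 the call of Scn9a was lost (adjusted p = 0.0515), and that of Snap25 without control 1, TRIM71 2 or TRIM71 3 (adjusted p = 0.0977, 0.0686 and 0.0934). With limma on log2 TPM with a pseudocount of 1 both were lost (adjusted p = 0.0597 and 0.256), and that of Snap25 also with counts scaled from TPM (0.151) and with protein-coding transcripts only (0.139). The neuronal list passed with the block (adjusted p = 0.00509), with library totals (0.0492), without control 3 (0.0160), without TRIM71 1 (0.0449) and without TRIM71 2 (0.00500), but not with an estimated correlation (adjusted p = 0.678 with an estimated correlation, and 0.492 with the block as well). Its mean level per library ran from -0.88 in control 2 to 1.16 in TRIM71 3, relative to the mean of the 6 libraries.

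Of 14 Schwann cell and glia genes Pmp22 and Ncam1 rose and Cnp fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.888), with a median log2 fold change of -0.19 and a mean of 0.25, and 4 rose and 2 fell without control 2. Ncam1 lost its call with counts scaled from TPM (adjusted p = 0.111) and with limma on log2 TPM with a pseudocount of 1 (0.104). Of 14 genes of endothelium and pericytes Egfl7 and Cspg4 rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.770), with a median of -0.06 and a mean of 0.09. Without control 2, 4 rose and 2 fell. The number called was 1 without control 1, control 3, TRIM71 2 or TRIM71 3, where Cspg4 had adjusted p = 0.115, 0.0520, 0.135 and 0.0684. Cspg4 lost its call with limma on log2 TPM with a pseudocount of 1 (adjusted p = 0.0931) and Egfl7 with protein-coding transcripts only (0.0737). Of 9 macrophage genes Aif1 fell (0 adjusted over the list alone; camera adjusted p = 0.0864). Its call was lost without each library other than control 2 (adjusted p between 0.0546 and 0.128) and with counts scaled from TPM (0.0835), while without control 2 the list was called as lower with 3 members fallen (adjusted p = 0.0471), as many as the block called. Over all libraries its adjusted p = 0.479 with an estimated correlation. Of 4 red blood cell genes Alas2 fell (1 adjusted over the list alone; camera adjusted p = 0.420), and lost its call, leaving 0 called, without control 1, control 3, TRIM71 1 or TRIM71 2 (adjusted p = 0.0651, 0.0521, 0.0675 and 0.0767). Without control 2, 2 red blood cell genes fell.

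Of 18 FGF and ERK feedback genes 9 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.000656; adjusted p = 0.247 with an estimated correlation). The ERK phosphatase gene Dusp6 rose by 1.46 ± 0.12 on the log2 scale, Spry2 by 1.02 ± 0.12, Spred2 by 0.92 ± 0.10 and the transcription factor Etv1 by 1.67 ± 0.18. Spry1 and Fgfr1 fell (chosen after their values were seen; Spry1 adjusted p = 0.0653 and 0.0580 without control 1 and TRIM71 2; Fgfr1 adjusted p = 0.0739, 0.0565, 0.0724, 0.130 and 0.125 without control 1, control 3, TRIM71 1, TRIM71 2 and TRIM71 3). Called members numbered 7 without control 1 and 5 without TRIM71 2. Of 22 Wnt targets 8 rose and 2 fell (13 and 2 adjusted over the list alone; camera adjusted p = 0.000452; adjusted p = 0.247 with an estimated correlation), and 14 rose and 3 fell without control 2. The Wnt inhibitors Apcdd1, Nkd2 and Notum rose by 1.83 ± 0.14, 1.76 ± 0.18 and 2.85 ± 0.30; with counts scaled from TPM the rise of Apcdd1 was 3.10. Tnfrsf19 and Znrf3 fell (chosen after their values were seen; Znrf3 adjusted p = 0.107, 0.0793 and 0.0931 without control 1, TRIM71 2 and TRIM71 3). Of 23 BMP pathway genes 10 rose and 1 fell (11 and 2 adjusted over the list alone; 13 and 3 with the block; camera adjusted p = 0.000510; adjusted p = 0.444 with an estimated correlation). Smad9 rose by 2.84 ± 0.35, the BMP antagonist Grem1 by 1.98 ± 0.28 and the pseudoreceptor Bambi by 1.54 ± 0.21. Atoh8 fell (chosen after its values were seen; adjusted p = 0.105, 0.0623, 0.0548, 0.104, 0.0794 and 0.0678 without control 1, control 2, control 3, TRIM71 1, TRIM71 2 and TRIM71 3).

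The TGF-beta and activin list went both ways, with 9 of 28 genes risen and 5 fallen (9 and 5 adjusted over the list alone; camera adjusted p = 0.183). The inhibitory Smad7 rose by 1.69 ± 0.17 on the log2 scale, the corepressor Tgif1 by 1.20 ± 0.12 and the activin receptor gene Acvr2b by 1.21 ± 0.15. Tgfbr3 fell by 1.54 ± 0.17, together with Ccn2 and, chosen after their values were seen, Ltbp2, Acvr1 and Ski (Acvr1 adjusted p = 0.121, 0.0725, 0.0741, 0.171 and 0.143 without control 1, control 2, TRIM71 1, TRIM71 2 and TRIM71 3; Ski adjusted p = 0.129, 0.0587, 0.109, 0.116 and 0.130 without control 1, control 2, TRIM71 1, TRIM71 2 and TRIM71 3). Called members numbered 9 without control 1 and 9 without TRIM71 2. Of 23 Notch pathway genes 8 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.0360; adjusted p = 0.472 with an estimated correlation). Hes1 rose by 1.39 ± 0.25 and the ligand gene Jag1 by 0.90 ± 0.19. Maml2 fell (chosen after its values were seen; adjusted p = 0.0641, 0.0631 and 0.0624 without control 1, TRIM71 2 and TRIM71 3). The Notch list's call was lost without control 1 (adjusted p = 0.0549), control 3 (0.0553) or TRIM71 3 (0.05002), with fry (0.0616) and with protein-coding genes only (0.0547). With the block 10 Notch genes rose and 4 fell, and the number called was 3, 5, 4 and 5 without control 1, control 3, TRIM71 2 and TRIM71 3. Of 20 YAP and TEAD targets 4 rose and 6 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.559), and 6 were called without control 1. Crim1 rose by 0.93 ± 0.17, with Ccn1, Dock5 and Fjx1 (chosen after their values were seen; Ccn1 adjusted p = 0.0848, 0.0658, 0.101 and 0.0743 without control 1, control 3, TRIM71 2 and TRIM71 3; Dock5 adjusted p = 0.0795, 0.0682 and 0.0502 without control 1, TRIM71 1 and TRIM71 3; Fjx1 adjusted p = 0.0906, 0.0756, 0.0944 and 0.0937 without control 1, control 3, TRIM71 1 and TRIM71 3). Nuak2 fell by 1.23 ± 0.21.

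Of 25 cholesterol synthesis genes 17 rose and 1 fell (20 and 1 adjusted over the list alone; camera adjusted p = 3.22e-08; adjusted p = 0.295 with an estimated correlation). The sterol sensor partner Insig1 rose by 0.89 ± 0.10 on the log2 scale, Dhcr7 by 0.96 ± 0.12 and Lss by 0.83 ± 0.09 (2.04 with protein-coding transcripts only). Of 25 genes of the integrated and endoplasmic reticulum stress responses 10 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.000247; adjusted p = 0.295 with an estimated correlation). Those with the smallest p handle amino acids and folate: the transporter genes Slc7a5 and Slc3a2 rose by 2.32 ± 0.17 and 0.96 ± 0.11, asparagine synthetase Asns by 1.53 ± 0.13 and Mthfd2 by 1.49 ± 0.16. Psat1 fell (chosen after its values were seen; adjusted p = 0.0987, 0.0510, 0.0742, 0.125 and 0.144 without control 1, control 2, TRIM71 1, TRIM71 2 and TRIM71 3). Of 26 p53 targets 13 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 5.53e-05; adjusted p = 0.472 with an estimated correlation). Psrc1 and Ckap2, which also act on the mitotic spindle and are in the G2 and M phase list, rose by 2.02 ± 0.24 (2.72 with protein-coding transcripts only) and 1.68 ± 0.21, and Perp, a desmosome protein, fell by 1.13 ± 0.15. Called p53 targets numbered 6, 7, 8 and 7 without control 1, control 3, TRIM71 2 and TRIM71 3, and the list was not called by fry (adjusted p = 0.0895). Of 30 interferon response genes 0 rose and 5 fell, among them Parp14, Gbp2, Ifih1 and Gbp3 (0 and 5 adjusted over the list alone; camera adjusted p = 0.0770). Each of these 4 falls lost its call without TRIM71 2 (adjusted p = 0.0631, 0.105, 0.104 and 0.0838), and Gbp3 was chosen after its values were seen (adjusted p = 0.127, 0.0642, 0.0838 and 0.0868 without control 1, TRIM71 1, TRIM71 2 and TRIM71 3). Other losses were those of Parp14 without control 1 and TRIM71 1 (0.0592 and 0.0509), of Gbp2 without control 1 and TRIM71 3 (0.0751 and 0.0801) and of Ifih1 without control 1, control 3 and TRIM71 1 (0.0657, 0.0712 and 0.0854). With limma on log2 TPM the calls of Gbp2 and Ifih1 were lost with a pseudocount of 1 (0.0581 and 0.0548) and that of Parp14 with 0.1 (0.0558), and with counts scaled from TPM that of Ifih1 (0.0521). Without control 2, 1 interferon gene rose and 7 fell. The number called was 1 without control 1, 2 without TRIM71 1, 0 without TRIM71 2 and 3 without TRIM71 3, and the list was called as lower without control 3 (adjusted p = 0.0241) and by fry (adjusted p = 0.0173), with an adjusted p = 0.295 with an estimated correlation over all libraries.

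In glycolysis, hypoxia, ribosomal and respiratory genes, control 2 lay above the other controls and below every TRIM71 library. The mean level of the glycolysis and hypoxia list, in log2 CPM relative to the mean of the 6 libraries, was -0.87, 0.32 and -1.39 in controls 1, 2 and 3 and 0.54, 0.72 and 0.68 in TRIM71 1, 2 and 3. Of its 32 genes 6 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 4.84e-08; adjusted p = 0.472 with an estimated correlation), and without control 2 the number was 30, with the median log2 fold change at 1.51 in place of 0.87. Ankrd37 rose by 2.06 ± 0.33 and the vasoactive peptide gene Adm by 1.72 ± 0.35, both hypoxia-responsive. Of 82 cytosolic ribosomal protein genes 16 rose and 0 fell (0 adjusted over the list alone; camera adjusted p = 1.09e-10; adjusted p = 0.472 with an estimated correlation), and 64 without control 2. The mean level of this list was -0.23, -0.0016 and -0.34 in controls 1, 2 and 3 and 0.07, 0.19 and 0.32 in TRIM71 1, 2 and 3. Rpl12, for example, rose by 0.52 ± 0.11, with adjusted p = 0.0556 without control 1, 0.0605 without TRIM71 2 and 0.0779 with protein-coding transcripts only. Of 86 nuclear respiratory chain genes 10 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.000252; adjusted p = 0.487 with an estimated correlation), and 28 rose and 2 fell without control 2. Their mean level was -0.18, 0.06 and -0.24 in controls 1, 2 and 3 and 0.07, 0.10 and 0.19 in TRIM71 1, 2 and 3. Cox6b2 rose by 1.42 ± 0.24, and Ndufa1 fell by 0.71 ± 0.16 (adjusted p = 0.0665, 0.0661 and 0.0534 without control 1, TRIM71 2 and TRIM71 3).

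Without control 1, control 3, TRIM71 1, TRIM71 2 and TRIM71 3, the ribosomal protein genes called numbered 0, 2, 4, 0 and 2 and the respiratory chain genes 1, 4, 5, 2 and 2, while glycolysis and hypoxia genes numbered 2 without control 1 and 3 without TRIM71 2. With the block 34 ribosomal genes rose and 0 fell, 16 respiratory genes rose and 2 fell, and 14 glycolysis and hypoxia genes rose and 0 fell, while counts scaled from TPM gave 5 ribosomal and 7 respiratory genes. The lists of ribosomal, glycolysis and respiratory genes were not called by fry (adjusted p = 0.0724, 0.103 and 0.0948). None of 13 mitochondrially encoded mRNAs passed the edgeR test (0 adjusted over the list alone; camera adjusted p = 0.654), while with the block 1 rose and 4 fell, without control 2, 2 rose and 0 fell, and with library totals 1 passed. The largest of these differences by p was that of mt-Cytb, with a log2 fold change of -0.51 ± 0.19 (adjusted p = 0.0816; 0.0129 with the block, 0.0353 with DESeq2, 0.0454 with upper-quartile factors and 0.0465 with library totals).

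**Figure D3:**
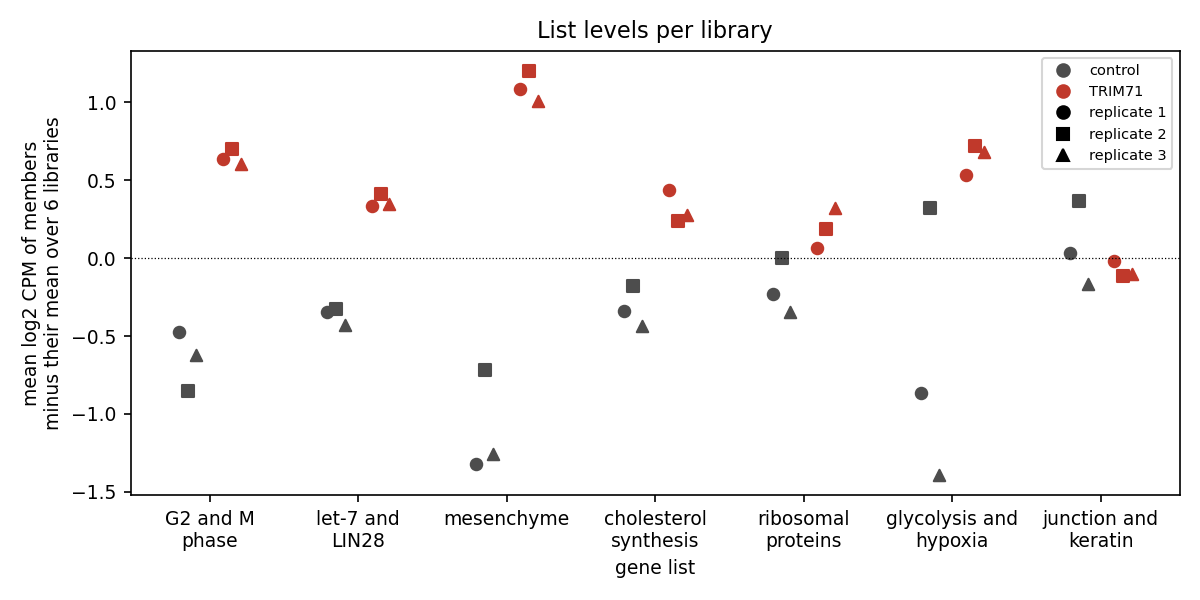
Mean log2 CPM of the members of 7 gene lists minus their mean over the 6 libraries (vertical axis) for each list (horizontal axis); each symbol is a library, grey for controls and red for TRIM71, with the shape giving the replicate number. Controls and TRIM71 libraries are apart in the G2 and M phase, let-7 and mesenchyme lists, while control 2 lies at 0.32 in the glycolysis and hypoxia list, far above the other controls at -0.87 and -1.39.

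In all, camera called 20 of the 36 lists, 19 as higher and 1 as lower. With a correlation estimated per list 0 of 36 passed, and 6 had an unadjusted p under 0.05. Of 62775 transcripts tested with edgeR, 1708 passed, of which 927 rose and 781 fell. With the block 0 transcripts passed (12727 had an unadjusted p under 0.05), while DESeq2 without the block called 6426. Without control 1, control 2, control 3, TRIM71 1, TRIM71 2 and TRIM71 3 the number of transcripts was 7, 2663, 165, 1, 2 and 12.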

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

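The alternatives were chosen before the data were examined, apart from counts of protein-coding transcripts only, which were chosen after seeing the data. Against 4626 called genes (2466 rose, 2160 fell), the other scalings, filters, units and tools and the replicate block gave between 3509 (limma on log2 TPM with a pseudocount of 0.1) and 6073 genes, and protein-coding transcripts only gave 3953. A test against a 1.5-fold change gave 1110 genes, of which 686 rose and 424 fell, since by construction it asks for a larger change. Leaving out 1 library gave 2208 to 6976 genes, with 1291 to 3715 risen and 906 to 3261 fallen. The lowest count came without TRIM71 2 and the highest without control 2. Fewer samples were left in each of these. Control 2 was the control nearest to the TRIM71 libraries on the first principal component (-27.0, against -59.9 and -65.9 for controls 1 and 3). How far this accounts for the higher count without control 2 was not tested, and why control 2 lay there was not settled.

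Against 1708 called transcripts, DESeq2 gave 6426, a minimum of 10 counts in all libraries 3336 and the replicate block 0 (12727 at an unadjusted p under 0.05). The cause was not tested. Leaving out 1 library gave 1 to 2663 transcripts. Against 20 called lists, an estimated correlation gave 0 (6 at an unadjusted p under 0.05). By fry 14 of the 20 passed and 2 others did, library totals gave 22, protein-coding genes only 18, the block 25 and leaving out 1 library 18 to 24.

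The replicate block gave 6073 genes (3239 rose, 2834 fell), of which 4603 were among the 4626 called without it, so it added 1470 gene calls and ended 23. Among 164 named genes it added 12 calls and ended 0, and among the lists it added 5 and ended 0. Apart from these, the transcripts and unnamed genes it changed no other call. Over 3253 combinations of a named gene and an alternative, 2984 kept their side of the threshold, 69 passed anew and 200 no longer passed. Among combinations called in the main fit or in the alternative, 0 changed direction. Changes of direction without a call in either were not counted. With changes planted in simulated counts, the edgeR test found 97.0% of 4-fold, 68.7% of 2-fold and 10.4% of 1.5-fold changes, with 200 genes changed, all above a minimum mean count in controls. So few changes set a stricter threshold than in the real data, and the share missed there was not measured. Genes with few counts had uncertain folds.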

Other observations

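The tests on mesenchymal genes, on mixing into control 2, on retained introns and on let-7 sites were chosen only after the patterns they address were seen. For retained introns and let-7 sites the values expected were set before the test was run, and the other splits of the libraries were planned. Transcripts annotated as retained introns held 11.9, 9.40 and 14.5% of the counts in controls 1, 2 and 3 and 10.9, 11.5 and 11.4% in TRIM71 1, 2 and 3.

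Mesenchymal genes were higher with TRIM71, with a mean log2 fold change of 2.32 ± 0.72 over the 19 members of the list but a median of 1.16, as genes near absent from controls (among them Twist2 and Col3a1) carry part of the mean. A lower share of epithelial cells would raise the markers of every other cell type alike. The means of 3 other lists lay below 0 and under the mesenchyme mean by over 2 standard errors over members (macrophages -0.61 ± 0.24, stria -0.56 ± 0.33, and red blood cells -0.23 ± 0.39 with 4 genes). These errors take members as independent and do not measure the spread between libraries. The mean levels of the macrophage and stria lists were lower in every TRIM71 library than in every control, while those of red blood cells overlapped. This argues against a lower share of epithelial cells as the whole cause. Neurons (0.88 ± 0.25), roof epithelium (0.81 ± 0.35), Schwann cells (0.25 ± 0.33) and endothelium (0.09 ± 0.21) had means above 0 (medians: macrophages -0.55, stria -0.52, red blood cells -0.44, neurons 0.97, roof epithelium 0.89, Schwann cells -0.19, endothelium -0.06). Growth of mesenchymal cells in the TRIM71 cultures may still account for the rise: of 6 members under 2 CPM in controls, 4 rose (Twist2, Pdgfrb, Col3a1 and Col1a2) and Coch and Pou3f4 did not pass (chosen after their values were seen). That result lies between the values named for such growth and for its absence, which were not set before the test was run. A change of state in epithelial cells cannot be told apart from such growth here, because bulk RNA does not show which cells carry a transcript. Of the 19 members 13 stood at 2 CPM or more in controls, where the abundant Lum and Dcn (also chosen after their values were seen) stood at similar means in both groups (log2 fold change 0.01 ± 0.26 and -0.01 ± 0.38), and 4 are also in another list.

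Control 2 lay 38.3% of the way from the other controls to the TRIM71 libraries on the axis between the groups, where controls 1 and 3 lay at 2.15 and 1.94%. Each control was placed against the mean of the other controls, which for controls 1 and 3 includes control 2, so these percentages are not on the same scale. Noise in that mean enters both the axis and the place, which raises each percentage somewhat. Mixing of TRIM71 RNA or reads into control 2 might be expected, but 5 genes near absent from the other controls (Cbln2, Col3a1, Crabp1, Sall4 and Twist2) stood in control 2 at a median of 0.425% of the TRIM71 level and at most 2.43%. The place on the linear scale, on which mixing acts, was read over called genes that changed at least 4-fold. These were chosen in the main fit with control 2 among the controls, which can draw the place of control 2 towards 0. Over genes risen at least 4-fold, control 2 had a median place of 4.12% (other controls -4.29 and -2.41%). Over genes fallen at least 4-fold its median place was 32.8% (others -20.5 and -5.47%), where 1 mixed share would give the same value to both. Mixing is therefore argued against as the whole cause. A share of a few percent would set all 5 genes named above at that percent of the TRIM71 level or higher. Col3a1, Crabp1, Sall4, Twist2 and Cbln2 stood at 0.0602, 0, 0.425, 1.22 and 2.43%, so only a smaller share stays open. Its lower share of retained-intron transcripts was also argued against, as the whole cause, since control 2 still lay 33.997% of the way with protein-coding transcripts only. A difference between the animals or cultures stays open and was not tested.

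Lin28a and Lin28b, which block let-7, were higher with TRIM71, and lower let-7 activity is a candidate explanation for higher levels of mRNAs that carry its sites. Over 15822 genes with an annotated 3' UTR (84.2% of tested genes), the let-7 seed match, present in 1594, had a coefficient of 0.044 ± 0.021 on the log2 fold change, rank 3 among all rearrangements of its bases, as foreseen; their median was -0.019. Without the members of the let-7 list the coefficient was 0.034 ± 0.021, at rank 4. The errors of both coefficients are standard errors over genes taken as independent. They do not measure the spread between libraries. The effect is very small beside the changes of Igf2bp1 and Hmga2, and let-7 itself was not measured.

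The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4626 genes and 1708 transcripts, and the highest of the others 0 and 0, so 1 of 10 splits gave as many genes and 1 of 10 as many transcripts. Every other split puts control and TRIM71 libraries into the same group. A difference between control and TRIM71 then adds to the spread within groups, so low counts of genes and transcripts were likely in advance. They do not show what chance alone would give. For the lists, 2 of 10 splits gave as many: the real one with 20, and controls 1 and 3 with TRIM71 3 against the rest with 23. That split leaves control 2 with TRIM71 1 and 2. Every other split gave lists too, from 9 to 23, so this count does not set the real split apart. The deviations of control and TRIM71 libraries with the same number were correlated (0.43, 0.23 and 0.37), and the 3 other splits that part all numbers gave 0 genes and 10, 18 and 14 lists.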
